A study of Mus musculus with 8 samples.

How the data were processed

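RNA from primary mouse microglia was sequenced in 8 libraries, 4 from cells given T3 (liothyronine, the receptor-binding form of thyroid hormone) and 4 from cells given none. The group of each library is the one its treatment label gives. That label says no treatment for the second group, while the treatment protocol says vehicle; the group is called untreated here, and which of these it received is not settled by the sources used here. The short sample titles call the T3-treated libraries con and the untreated ones Hypo, and the same titles number the libraries 1 to 4 in each group. The labels do not say whether the libraries of a group came from separate cultures, litters or days, so p-values measure only the spread between these samples.

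Per the submitters' processing notes, the tools used upstream included STAR, with no version named, and RSEM 1.3.3, and the genome build was mm10. The annotation release is not given in the sources used here. Per the labels' protocols, the libraries were made from total RNA with a stranded kit. Whether RSEM counted by strand is not given in the sources used here, so reads in a stretch that genes share on opposite strands cannot be told apart. Per the file headers, the deposited expected counts are RSEM's estimates of the reads of each gene, not scaled for depth, in which a read that matches several genes is shared among them. Of all these values, those of genes without a count included, 7.91% were not whole numbers. Per the file headers, the authors also deposited TPM and FPKM values made by RSEM. The TPM values entered an alternative test and the FPKM values were not used. Gene lengths and effective lengths in bases came from the same deposited tables and entered the gene-length correction.

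Each table listed 47643 genes with an Ensembl identifier and a symbol, and 126 symbols occurred more than once. Coordinates and gene types were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names, in which 47224 of the identifiers were found. Coordinates are 1-based. The library totals lay between 19.3 M and 26.6 M counts (M, mega). Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom between 4.31 and 29.5 for pairs of libraries over genes with at least 10 counts in the pair, so no library was treated as a copy of another.

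The expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr on the groups, which left 13004, and libraries were scaled by TMM factors. Differences were tested by edgeR's quasi-likelihood F-test, T3 over untreated, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic, and intervals are 95% intervals from these errors. Levels are CPM, the share of a library's TMM-scaled total in parts per mega, given as mean ± SD with n = 4 per group. At these depths the median half-width of the interval was 0.19 on the log2 scale among the 8469 genes with a mean of at least 10 CPM.

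Before the data were examined, 31 gene lists, the design, the alternatives and the rule for naming genes were fixed. The lists cover T3 target genes, thyroid hormone handling, microglial states, immune pathways, metabolism, cell cycle, stress, the circadian clock, the lysosome and markers of other cell types a brain culture can hold. Lists with at least 3 tested members were tested with camera from limma 3.58.1 on voom-transformed counts, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists tested. Each list was also tested with an estimated correlation, and by fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. A larger p with an estimated correlation need not come from members that vary together. Unpaired, the estimate was -0.0012 for the neuron list and -0.16 for the T3 target genes, below the preset. Members were counted as risen, fallen or not past the threshold over all genes tested and adjusted over the list alone. Genes named are up to 10 per direction with the largest change among those past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes and structural RNAs. A fixed set of thyroid and microglial genes was also named, and, per list, up to 2 members per direction with the smallest p. Genes named outside this rule are said to be chosen after their values were seen.

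The replicate numbers may pair samples, and this was checked on the deviations of log2 CPM from the group means, across genes. Libraries with the same number in the 2 groups correlated at 0.19, 0.25, 0.40 and 0.43, all above the limit of 0.1 set beforehand. By that limit alone the numbers were taken to pair the libraries. The pairing comes from the titles' numbers and the data, and nothing in the labels states it. Pairs with different numbers correlated between -0.44 and 0.43, and 5 of the 8 libraries correlated best with the one of their own number. T3 replicate 1 with untreated replicate 4 gave 0.43, 4 with 1 gave 0.29, 3 with 2 gave 0.38 and 2 with 3 gave 0.21. The limit therefore cannot tell pairing by number from a division of numbers 1 and 4 from 2 and 3. Where a fit is called paired, only the block by replicate number is meant. A fit with the replicate number as a block of 4 levels was therefore set beside the unblocked fit, which stays the primary one, wherever it changed a call or moved a count by over 1.5 times.

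The alternatives were other scaling factors (DESeq2's size factors, upper-quartile factors, library totals), DESeq2 1.42.0 and limma-voom as tests, and other low-count filters (none, or 1 CPM in 4 libraries). Further ones were the replicate block, a gene-length correction by per-library lowess offsets with a span of 0.3, with and without the block, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a test against a fold of 1.2, removal of mitochondrial and small RNA genes, and each library left out in turn. Fits within subsets of the replicate numbers, and alternatives to the blocked fit, were added after the data were seen.

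The procedure was tested on counts simulated from the means, dispersions and library sizes of this comparison for 12847 genes. The unblocked fit recovered 56.9% of 65 genes changed 1.5-fold, 86.2% of 65 changed 2-fold and 98.5% of 65 changed 4-fold, with 18 unchanged genes called. The blocked fit recovered 53.8%, 83.1% and 98.5%, with 10 unchanged genes called. In a simulation over 30 lists, 3 of 3 raised lists and 0 unchanged lists were called. The simulated counts were drawn independently for each gene and library, without the structure by replicate number of the real libraries. They therefore cannot show how often unchanged genes or lists are called in the real libraries, or what the block gains there. Overlaps were read from the gene bounds, introns included, and reads in a shared stretch can belong to either gene. Some are given beside the gene; Gpr34, S100b, Per3, Bcas1, Pfkfb3, Fgfr3, Dio2, Srebf1, Tnr and others named also overlap a neighbour.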

Results

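Gene expression was measured by RNA sequencing in primary microglia, the macrophages of the brain, grown from the cortex and hippocampus of newborn CD1 mice (postnatal day 1). The cells were harvested as the floating fraction of mixed brain cultures at 11 to 12 days, replated, and kept for 48 h with 0.3 µM T3 or without it. Each group had 4 libraries. The total expected count was 21.8 ± 2.0 M per library (SD, n = 4) with T3 and 23.6 ± 2.28 M without, over a range of 19.3 M to 26.6 M. The difference did not pass the test (two-sided exact permutation test, p = 0.371, adjusted p = 0.886 over 6 library measures). Between 16656 and 17758 genes had at least 1 count in a library. Mitochondrially encoded genes took 2.09 ± 0.209% of counts with T3 and 2.06 ± 0.191% without (two-sided exact permutation test, p = 0.8, adjusted p = 0.886). Genes of ribosomal proteins took 2.54 ± 0.326% and 2.77 ± 0.368% (two-sided exact permutation test, p = 0.314, adjusted p = 0.886). For replicate numbers 1 to 4 in order, the share was 2.343, 2.535, 3.003 and 2.284% with T3. Without T3 it was 2.483, 2.979, 3.184 and 2.439%, higher at each number. These tests did not use the replicate numbers.

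The comparison of T3-treated with untreated cells asks which genes of these microglial cultures respond to thyroid hormone. With T3, 9 of 13004 tested genes rose, among them Hr, a nuclear corepressor and known direct target of the thyroid hormone receptor, which rose 8.30-fold from 0.618 ± 0.326 to 5.21 ± 0.909 CPM. Dbp, a transcription factor of the circadian clock, rose 1.91-fold from 7.23 ± 0.791 to 13.8 ± 1.33 CPM. Scd1, a fatty acid desaturase, rose 2.46-fold, and Acsbg1, an acyl-CoA synthetase, 3.80-fold. Abcb4, a phosphatidylcholine transporter and the most abundant gene of the 9, rose 1.38-fold from 28.3 ± 1.06 to 39.1 ± 1.33 CPM. Of the 9, 7 had a mean under 10 CPM. Whether the microglia or other cells in the cultures carried the rise was not tested. Genes of cytokines and of microglial states did not pass the threshold in either direction.

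By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of Hr (ENSMUSG00000022096, chromosome 14, 70552212 to 70573548 in GRCm38, as are all coordinates here) was 3.05 ± 0.284 (SE), adjusted p = 0.00359. Col11a1, a fibrillar collagen chain (ENSMUSG00000027966, chromosome 3, 114030540 to 114220718), rose by 2.46 ± 0.321 on the log2 scale from 0.381 ± 0.0952 to 2.11 ± 0.758 CPM, adjusted p = 0.0218. Chrna4, a nicotinic acetylcholine receptor subunit (ENSMUSG00000027577, chromosome 2, 181018380 to 181043546), rose by 2.04 ± 0.238 from 0.402 ± 0.0544 to 1.67 ± 0.324 CPM, adjusted p = 0.0123. Acsbg1 (ENSMUSG00000032281, chromosome 9, 54604877 to 54661870) rose by 1.93 ± 0.212 from 0.956 ± 0.253 to 3.66 ± 0.636 CPM, adjusted p = 0.0120. Atp1b2, a beta subunit of the sodium pump (ENSMUSG00000041329, chromosome 11, 69599736 to 69605942), rose by 1.34 ± 0.184 from 3.41 ± 0.614 to 8.62 ± 2.04 CPM, adjusted p = 0.0308. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879) rose with an interval of 0.95 to 1.64 for its log2 fold change, from 1.31 ± 0.140 to 3.22 ± 0.313 CPM, adjusted p = 0.0123. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) rose by 0.94 ± 0.107, adjusted p = 0.0123. Its end overlaps that of Sphk2 on the opposite strand, and reads in the shared stretch cannot be told apart. Abcb4 (ENSMUSG00000042476, chromosome 5, 8893717 to 8959231) rose by 0.47 ± 0.0584, adjusted p = 0.0164, and overlaps the predicted gene Gm17936 on its own strand. All are annotated as protein-coding.

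The gene with the largest fold of the 9, Adam11, a member of the ADAM family of membrane proteins (ENSMUSG00000020926, chromosome 11, 102761439 to 102780262), lay under the level set for naming and was named after its values were seen. It rose by 3.38 ± 0.301 on the log2 scale, from 0.118 ± 0.0255 to 1.27 ± 0.218 CPM (edgeR, adjusted p = 0.00359). For each of the 9 genes, all 4 T3-treated libraries lay above all 4 untreated ones. Over all tested genes the groups did not overlap at 317, or 2.44%, where chance gives 2.86% for exchangeable libraries. The libraries divided by replicate number in both groups, as given below, so the 2 shares cannot be set against each other as a test. No gene fell by edgeR's unpaired test, while the paired fit with the replicate block called 55 genes, 44 higher and 11 lower. Unpaired, at an unadjusted p under 0.05, 163 genes had a lower level and 240 a higher one, 403 in all, where chance gives 650 of the 13004. The paired fit had 1125 genes under that p. A block of 2 levels, numbers 1 and 4 against 2 and 3, had 1040. DESeq2 called 31 genes higher and 1 lower, Ugt1a9, which shares exons with its gene family, and limma-voom called 7 higher and 0 lower. Leaving out 1 library changed the count of 9 genes to 3 without T3 replicate 1, 4 without T3 replicate 2, 5 without T3 replicate 4, 3 without untreated replicate 1, 2 without untreated replicate 2 and 3 without untreated replicate 3. Hr and Adam11 passed in all 8 such fits, and the other 7 genes in 2 to 5 of them.

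**Figure D1:**
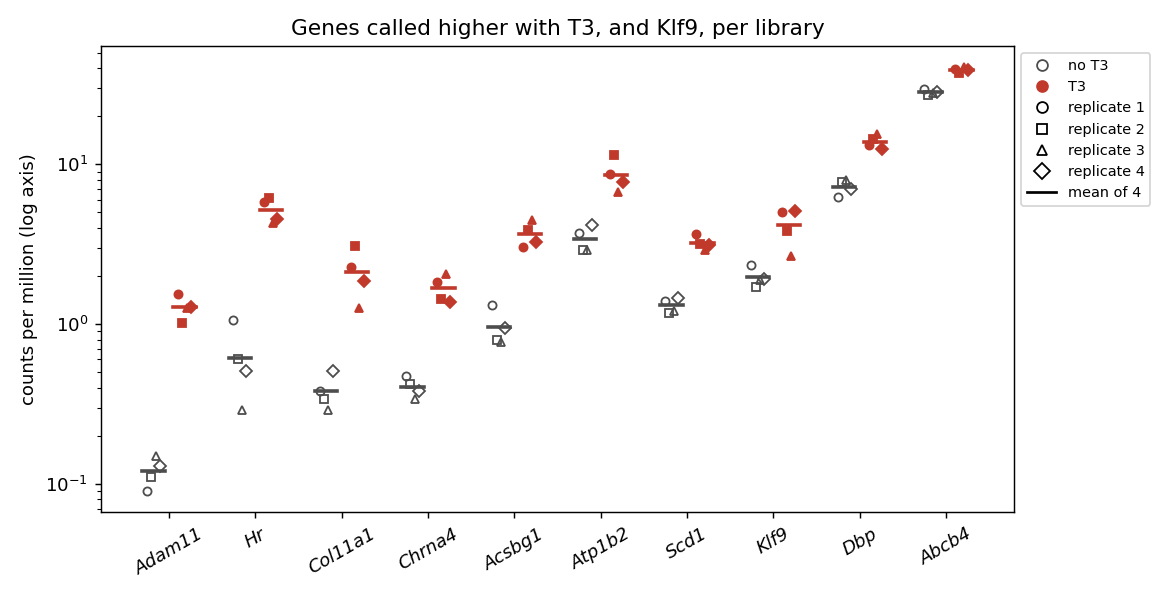
Level of each of the 9 genes higher with T3, and of Klf9, in each library, in CPM on a log axis, with open grey symbols for untreated and filled red symbols for T3-treated libraries, a symbol shape per replicate number and a bar at each group's mean. In every gene the T3-treated libraries lie above the untreated ones, for Hr between means of 0.618 and 5.21 CPM and for Abcb4 between 28.3 and 39.1 CPM.

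The list of T3 target genes was higher as a group with T3, with 6 of 6 tested members at a log2 fold change above 0 and a median of 0.60 (camera, adjusted p = 2.2e-09, and adjusted p = 0.0159 with an estimated correlation; adjusted p = 0.227 with an estimated correlation in the paired fit). Over all genes tested, Hr and Dbp rose and 4 did not pass. Adjusted over the list alone, Hr, Dbp and Klf9 rose. Klf9, a Krüppel-like transcription factor and direct target of the receptor (ENSMUSG00000033863, chromosome 19, 23141226 to 23168134), stood at 4.16 ± 1.15 CPM with T3 and 1.96 ± 0.271 CPM without, a log2 fold change of 1.09 ± 0.214. It did not pass over all genes (edgeR, adjusted p = 0.281) and did in the paired fit with the replicate number as a block (edgeR, adjusted p = 0.00679), which called it in 2 of the 4 fits without a pair. The target genes Dio3, Dio1, Thrsp, Nrgn, Itih3 and Thrb had too few counts to test. Of these, Dio3, the enzyme that inactivates T3, had 2 counts over all libraries and the receptor gene Thrb 49. None of the 18 tested genes of thyroid hormone handling passed, over all genes or adjusted over the list alone (camera, adjusted p = 0.994). Among them, the receptor gene Thra, which overlaps Nr1d1 on the opposite strand, had 9.25 ± 0.684 CPM with T3 and 9.54 ± 0.500 without, a log2 fold change of -0.04 with an interval of -0.24 to 0.15. Dio2, the activating deiodinase, was low, at 0.501 ± 0.226 CPM with T3, with a log2 fold change of 0.20 ± 0.455.

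Among metabolic groups, the fatty acid synthesis list was higher with T3 (camera, adjusted p = 0.00244), a call lost with adjusted p = 0.329 with an estimated correlation. Scd1 alone of 12 tested members rose, over all genes and adjusted over the list alone. Adjusted over the list alone in the paired fit, Scd1, Elovl6, Fads2, Fasn and Scd2 rose. Elovl6, an elongase, had a log2 fold change of 0.74 ± 0.257, and Srebf1, the transcription factor that drives the pathway, -0.03 ± 0.108. The circadian clock list was higher (camera, adjusted p = 0.0283; adjusted p = 0.330 with an estimated correlation). By camera it had an adjusted p of 0.089 and 0.108 without T3 replicates 1 and 4, and 0.111 and 0.159 without untreated replicates 2 and 3. Dbp was the only 1 of its 14 tested members to rise, over all genes and adjusted over the list alone. Clock and Per3 had log2 fold changes of 0.15 ± 0.122 and -0.05 ± 0.098. In the glycolysis list (camera, adjusted p = 0.411), 0 of 19 members passed over all genes and 1 rose adjusted over the list alone. This was Pfkfb3, a regulator of glycolytic flux, at 109 ± 6.53 CPM with T3 and 87.9 ± 6.89 without (edgeR, adjusted p = 0.506, and 0.0053 in the paired fit; called in 2 of the 4 fits without a pair). Slc16a1, a lactate transporter, rose adjusted over the list alone in the paired fit. Hk2, a hexokinase, stood at 57.6 ± 7.41 and 57.3 ± 4.35 CPM, a log2 fold change of 0.01 with an interval of -0.21 to 0.22. In the hypoxia response list (camera, adjusted p = 0.340), 0 of 14 members passed by either count. In the paired fit, adjusted over the list alone, Vegfa, Hif1a and Ero1l rose and Ndrg1 fell.

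Of the 46 nuclear-encoded genes of oxidative phosphorylation, 0 passed by either count (camera, adjusted p = 0.169). In the paired fit the list was lower (camera, adjusted p = 0.0149, and adjusted p = 0.797 with an estimated correlation), as it was unpaired without T3 replicate 3 (2.28e-05), untreated replicate 1 (0.00172) or untreated replicate 4 (0.000373). Of 13 mitochondrially encoded protein genes (camera, adjusted p = 0.535, and 0.0122 without untreated replicate 3), 0 passed by either count. The gene mt-Nd4l, which overlaps mt-Nd4, fell in the paired fit, from 97.5 ± 16.9 to 71.1 ± 10.7 CPM (edgeR, adjusted p = 0.0198, and 0.256 with the block and the length correction; called in 2 of the 4 fits without a pair). No member passed, over all genes or adjusted over the list alone, in the lists of the TCA cycle (camera, adjusted p = 0.681), cholesterol synthesis (0.203), LXR targets and lipid handling (0.681), fatty acid oxidation (0.414, and 0.0345 without T3 replicate 3), NRF2 targets (0.411, and 0.0304 without T3 replicate 4), cell cycle (0.462) and lysosome (0.681). The same held for 17 genes of ER and amino acid stress (camera, adjusted p = 0.0643), a list that was lower in the paired fit (camera, adjusted p = 0.0250, and adjusted p = 0.635 with an estimated correlation). Unpaired, it had a camera adjusted p of 0.0019 without T3 replicate 3, 0.0256 without untreated replicate 1 and 0.00628 without untreated replicate 4. Among its members, Trib3 and Phgdh had log2 fold changes of -0.28 ± 0.104 and -0.19 ± 0.0802.

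Genes of microglial states and immune activation did not pass the test. Of 17 tested homeostatic microglia genes, 0 passed over all genes or adjusted over the list alone (camera, adjusted p = 0.197). P2ry12, a purinergic receptor that overlaps Med12l on the opposite strand, had a log2 fold change of 0.17 with an interval of -0.01 to 0.35, at 8.93 ± 0.479 CPM without T3. Gpr34 had one of 0.26 ± 0.0758, which passed only in the paired fit adjusted over the list alone. Tmem119 was low in both groups, at 1.25 ± 0.164 and 1.16 ± 0.171 CPM. Cx3cr1, the fractalkine receptor, whose annotation overlaps several neighbours, stood at 73.9 ± 7.55 and 66.2 ± 7.94 CPM. Of 23 genes of disease-associated microglia, 0 passed by either count (camera, adjusted p = 0.209). In the paired fit the list was lower (camera, adjusted p = 0.0482, and adjusted p = 0.548 with an estimated correlation), as it was unpaired without T3 replicate 3 (0.0281). Its members Apoe and Trem2 were abundant, at 26170 ± 1280 and 1085 ± 68.6 CPM with T3, with log2 fold changes of -0.09 (interval -0.29 to 0.11) and -0.04 (interval -0.21 to 0.12).

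Of 19 tested genes of inflammatory cytokines and NF-kB targets, 0 passed by either count (camera, adjusted p = 0.361). Tnf stood at 12.2 ± 0.741 CPM with T3 and 12.8 ± 0.963 without, with an interval of -0.25 to 0.12 for its log2 fold change. Il1b, which overlaps an antisense gene, stood at 3.74 ± 0.329 and 3.58 ± 0.323 CPM, with an interval of -0.21 to 0.34. Il6 had 4 counts over all libraries and could not be tested at this depth. No member passed by either count in the lists of interferon response (19 tested, camera, adjusted p = 0.411), anti-inflammatory and alternative activation (9 tested, adjusted p = 0.411), phagocytosis and complement (23 tested, adjusted p = 0.650) and antigen presentation (15 tested, adjusted p = 0.203). The camera adjusted p of interferon response was 0.000209 without T3 replicate 1 and 0.0122 without untreated replicate 3, and that of antigen presentation 0.0166 without T3 replicate 2 and 0.0112 without untreated replicate 4. The members of these lists with the smallest p included Ifih1, an RNA sensor, with a log2 fold change of 0.21 ± 0.0707, Arg1, arginase, with -0.48 ± 0.195, Fcgr2b, an Fc receptor, with -0.13 ± 0.053, and Cd74 with -0.21 ± 0.0858. Each had an adjusted p of 1 over all genes (edgeR).

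**Figure D2:**
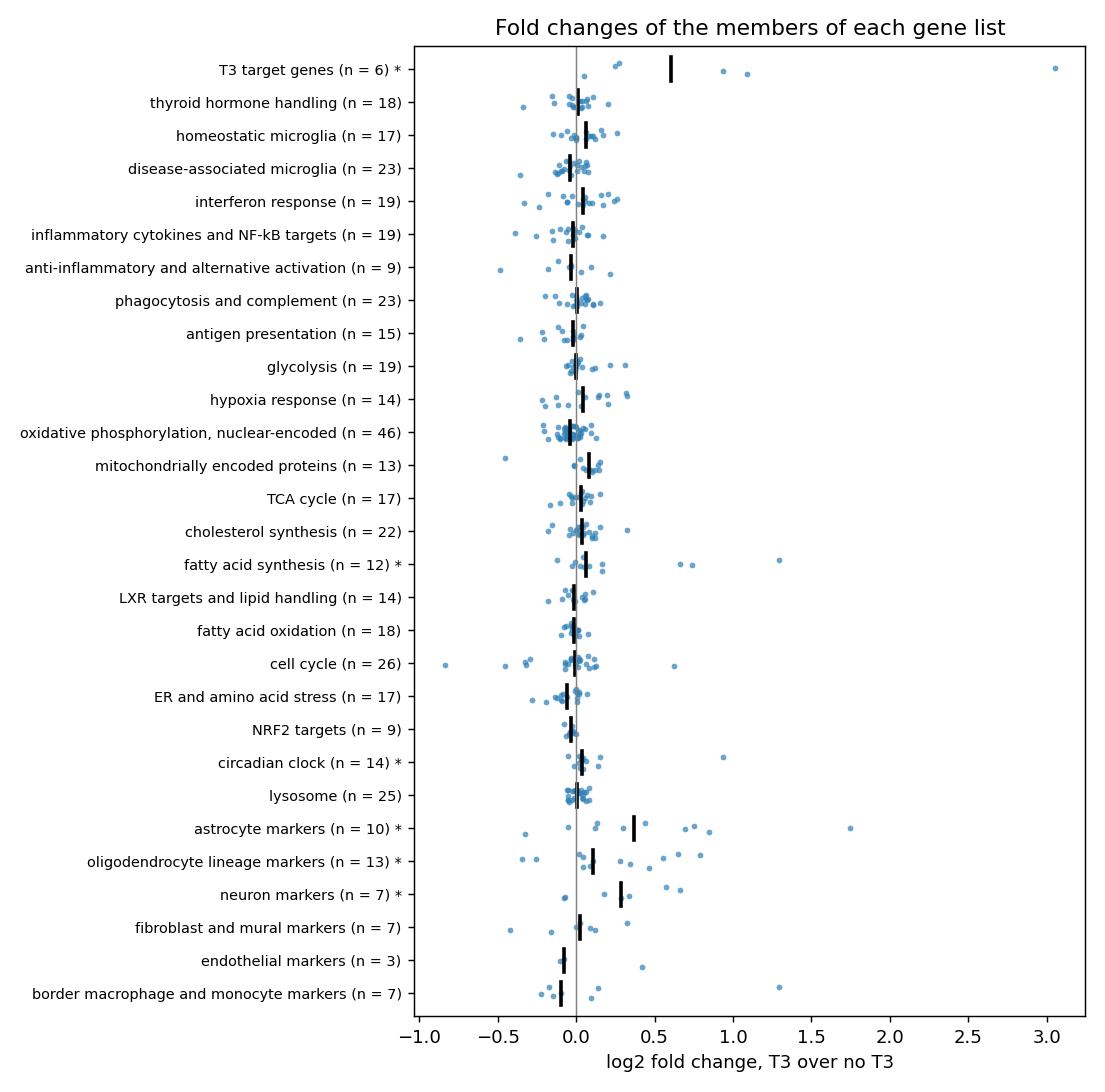
Log2 fold change, T3 over untreated, of each tested member (points) of the 29 lists with tested members, with a bar at the list's median and a star at lists past the threshold of the camera test. The T3 target genes have a median of 0.60, and the homeostatic and disease-associated microglia lists have medians of 0.06 and -0.04.

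The astrocyte list was higher with T3 (camera, adjusted p = 0.00331; adjusted p = 0.330 with an estimated correlation), a call also lost with genes kept at 1 CPM in 4 libraries (camera, adjusted p = 0.356). Of its 10 tested members, 0 passed over all genes, and Fgfr3 and S100b rose adjusted over the list alone, to which the paired fit added Gfap and Slc1a2. Fgfr3 had 0.927 ± 0.359 CPM with T3 and 0.276 ± 0.142 without, Gfap 2.72 ± 0.901 and 1.61 ± 0.583 CPM. The more abundant Aldh1l1 stood at 9.10 ± 0.931 and 9.44 ± 0.577 CPM and Slc1a3 at 4.90 ± 0.579 and 6.15 ± 1.60 CPM. The oligodendrocyte lineage list was higher (camera, adjusted p = 0.00333; adjusted p = 0.329 with an estimated correlation; camera adjusted p = 0.0515 without T3 replicate 2). Of its 13 members, 0 passed over all genes. Bcas1 rose adjusted over the list alone and, over all genes, in the paired fit (7.67 ± 0.866 against 5.21 ± 0.559 CPM; edgeR, adjusted p = 0.403, and 0.0334 with the block). That call of Bcas1 in the paired fit was lost with the length correction (adjusted p = 0.0513) and in all 4 fits without a pair. Gpr17 rose in the paired fit adjusted over the list alone. Olig2 had a log2 fold change of -0.34 ± 0.194, and Mbp, the most abundant of the list, stood at 111 ± 2.87 and 108 ± 2.98 CPM.

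The neuron list was higher (camera, adjusted p = 0.0476; adjusted p = 0.329 with an estimated correlation; 0.159 in the paired fit, 0.0516 with DESeq2's size factors). Without T3 replicates 1, 2 and 4 its camera adjusted p was 0.089, 0.153 and 0.108, and without untreated replicates 2, 3 and 4 it was 0.168, 0.0898 and 0.0659. It had 0 of 7 tested members past the threshold by either count. Its members Elavl4 and Rbfox3 had log2 fold changes of 0.66 ± 0.372 and -0.08 ± 0.241, at less than 1 CPM. The border macrophage and monocyte list did not pass (camera, adjusted p = 0.990). Over all genes 0 of 7 members passed, and Cbr2 rose adjusted over the list alone, at 0.770 CPM with T3 and 0.308 without. Fibroblast and mural markers (7 tested, camera, adjusted p = 0.872) and endothelial markers (3 tested, adjusted p = 0.681) had no member past the threshold by either count. The lists of lymphocyte and neutrophil markers and of ependymal and erythroid markers had 0 tested members, with at most 20 counts of S100a8 and 49 of Foxj1 over all libraries. The median, the mean and the test's direction differed in sign for the lists of thyroid hormone handling, glycolysis, border macrophages, fibroblasts and endothelium, none of which passed.

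With the replicate number as a block, edgeR's quasi-likelihood test called 55 genes, 44 higher and 11 lower with T3, the 9 genes above included. Genes named from this paired fit were chosen after their values were seen. Tnr, an extracellular matrix glycoprotein, rose from 2.57 ± 1.01 to 6.34 ± 1.58 CPM (edgeR with block, adjusted p = 0.000387). Klf13, a relative of Klf9, rose from 68.5 ± 15.5 to 92.2 ± 19.5 CPM (adjusted p = 0.0015). Slc43a2, an amino acid transporter, rose from 436 ± 80.8 to 578 ± 109 CPM (adjusted p = 0.0015). Tnr, Klf13 and Slc43a2 also passed in all 4 fits without a pair. Among the 11 lower genes were AY036118 and Rn18s-rs5, overlapping genes of ribosomal RNA sequence, the ribosomal protein genes Rps21 and Rpl27a, Tmsb10, and Ugt1a9, at 1.72 ± 0.0763 CPM with T3 and 6.88 ± 4.15 without. Of the 4 fits without a pair, AY036118 passed in 4, Rn18s-rs5 and Ugt1a9 in 3, Tmsb10 in 2, and Rps21 and Rpl27a in 1. AY036118, Rn18s-rs5 and Ugt1a9 overlap other genes and ribosomal protein genes have pseudogene copies, so their reads can be shared with those. Corrected for gene length as well, the paired fit called 31 genes, 28 higher and 3 lower, of which 30 were among the 55. Leaving out both libraries of replicate number 1, 2 or 4 changed the 55 to 96, 18 or 22.

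The libraries also differed in a way the treatment does not follow. The first principal component of log2 CPM held 41.1% of the variance and separated replicate numbers 1 and 4, between 9.16 and 21.8 on it, from numbers 2 and 3, between -25.0 and -6.19, in both groups. The second, with 14.5%, had the T3-treated libraries between 1.82 and 24.8 and the untreated ones between -15.5 and -3.41. Within numbers 1 and 4 alone, the test called 16 genes, and within numbers 2 and 3 alone 6, with 2 libraries per group. The log2 fold change of Hr was 2.70 ± 0.292 and 3.49 ± 0.353 in these subsets, with Dbp at 0.94 ± 0.123 and 0.92 ± 0.122, and Abcb4 at 0.43 ± 0.0739 and 0.50 ± 0.0881.

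**Figure D3:**
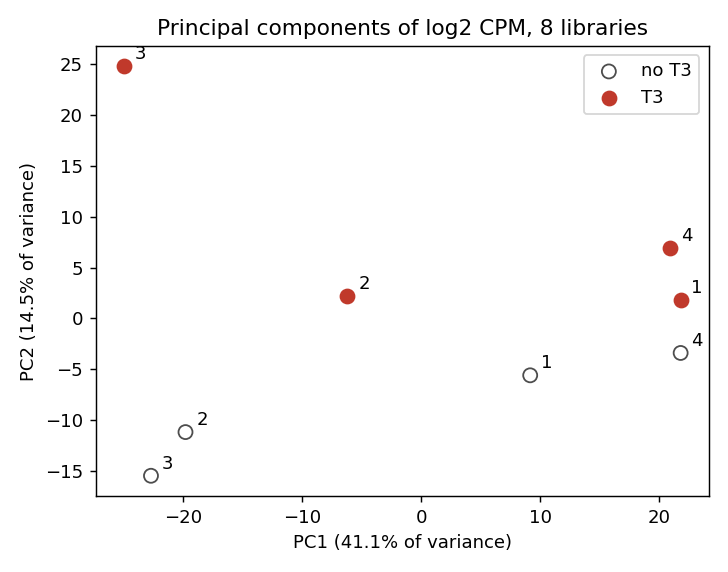
The 8 libraries on the first and second principal components of log2 CPM, with filled red points for T3-treated and open points for untreated libraries, each marked with its replicate number. Numbers 1 and 4 lie at 9.16 or above on the first component, which holds 41.1% of the variance, and numbers 2 and 3 at -6.19 or below.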

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

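The samples examined here were picked by a rule on the gap between 1 library and the rest of its group, fixed before the data were examined, and no test reported in this part was chosen after the result was seen. The rule was applied to 64 sets of 4 libraries, of which chance would mark about 3.2, and it marked 2. Cx3cr1 stood at 85.1 CPM in T3 replicate 2, while the other T3-treated libraries lay between 69.2 and 71.1 CPM. Untreated replicate 3 had 17265 genes with at least 1 count, while the other untreated libraries had 17651 to 17695. No explanation was tested for either value.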

How the results depend on the processing

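The fits within subsets of the replicate numbers and the alternatives to the paired fit were chosen after the data were seen. The count of 9 genes, all higher, was the same under the other scaling factors and lay between 7 and 10 under limma-voom, a test against a fold of 1.2, other low-count filters and without mitochondrial and small RNA genes. It became 32 genes (31 higher, 1 lower) by DESeq2, 55 (44 and 11) with the replicate block, 31 (28 and 3) with the block and the gene-length correction, 15 (all higher) with that correction alone, and 3 (all higher) on log2(TPM + 1) and on log2(TPM + 0.1). A block of 2 levels, numbers 1 and 4 against 2 and 3, gave 43 (39 and 4), numbers 1 and 4 alone 16 (12 and 4), and numbers 2 and 3 alone 6 (5 and 1). With 1 library left out it ranged from 2 to 12 genes, 2 to 11 higher and 0 to 1 lower, falling to 3, 4 and 5 without T3 replicates 1, 2 and 4 and to 3, 2 and 3 without untreated replicates 1, 2 and 3. The cause was not tested.

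In the paired fit, the 55 genes became 31 (28 and 3) with the length correction and 46 to 58 by DESeq2, limma-voom, another filter or scaling. Without 1 pair they ranged from 18 to 96, with 13 to 61 higher and 4 to 35 lower: 96 without number 1, 18 without number 2 and 22 without number 4. Of the 55, 13 passed in all 4 such fits. The 6 lists became 1 with an estimated correlation and 1 by fry, and ranged from 4 to 10 with 1 library left out, 10 being without T3 replicate 3. The 8 lists of the paired fit became 0 and 2 in the same tests and ranged from 2 to 9 without 1 pair, 2 being without number 2. Over 3185 values of 128 named genes, 3088 kept their side of the threshold, 59 were weaker, 38 stronger and 0 reversed, and 88 values of genes not past the threshold changed sign. Those kept include genes that stayed short of the threshold. Of the 9 called genes, Hr kept its call in 25 of 25 alternatives, Adam11 in 22, and Acsbg1 and Dbp in 21. Chrna4 kept it in 16, and Col11a1, Scd1, Atp1b2 and Abcb4 in 15. Of 375 for lists, 334 kept it, 24 were weaker, 17 stronger and 0 reversed. Besides the calls given with the block above, the block changed no other call of camera on a list. By fry, the circadian clock list passed with the block (adjusted p = 0.0484) and did not without it (adjusted p = 0.222). Genes under a few counts per library, such as Dio3 and Il6, are out of reach at 19.3 M to 26.6 M counts.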

Other observations

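The tests on astrocyte and oligodendrocyte-lineage markers and on the folds of the lower genes were chosen after the results were seen, as were the genes named here from the paired fit. Of the 44 genes higher in the paired fit, 20 had a mean of at least 10 CPM and small folds, between 1.16 and 1.91. They included Adcy7, an adenylate cyclase, at 353 ± 34.6 CPM with T3 and 281 ± 31.9 without (edgeR with block, adjusted p = 0.00679), and Slc27a1, a fatty acid transporter, at 196 ± 16.6 and 159 ± 5.11 CPM (adjusted p = 0.00699). Tfrc, the transferrin receptor, stood at 175 ± 13.9 and 148 ± 12.6 CPM (adjusted p = 0.0276), Mapk6, a protein kinase, at 115 ± 9.16 and 92.2 ± 7.41 CPM (adjusted p = 0.0053), and Cd38, an NAD glycohydrolase, at 47.2 ± 2.42 and 37.8 ± 2.77 CPM (adjusted p = 0.0198). T3-treated libraries were higher in all 4 pairs for each of these. Of the 4 fits without a pair, Adcy7 passed in 3, Slc27a1 and Mapk6 in 2, and Tfrc and Cd38 in 1, and with the block and the length correction Tfrc lost its call (adjusted p = 0.0809).

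The other 24 had a mean under 10 CPM and folds between 1.47 and 10.4. Besides those of the unpaired fit, they included Ptprz1, a receptor phosphatase, at 10.8 ± 1.59 and 7.13 ± 2.29 CPM (edgeR with block, adjusted p = 0.0198), Cntn1, a neural adhesion molecule, at 4.12 ± 0.506 and 1.84 ± 0.658 CPM (adjusted p = 0.00679), Cacng4, a regulator of AMPA receptors, at 3.30 ± 0.910 and 1.51 ± 0.470 CPM (adjusted p = 0.022), and Gpr37l1, an orphan receptor, at 1.12 ± 0.112 and 0.343 ± 0.0892 CPM (adjusted p = 0.0219). Cntn1 passed in 3 of the 4 fits without a pair and the other 3 genes in 1, and with the block and the length correction Ptprz1 (adjusted p = 0.0638) and Cacng4 (adjusted p = 0.0544) lost their calls. In the same fit the astrocyte and oligodendrocyte lineage lists were higher (camera, adjusted p = 0.0138 and 0.0104, and adjusted p = 0.591 and 0.548 with an estimated correlation).

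The 9 genes higher with T3 had a median log2 fold change of 1.93, and markers of astrocytes and oligodendrocyte-lineage cells were higher as lists. For the 9 genes a gene-length trend is argued against, since 9 of the 9 passed after its correction. A larger share of such cells in the T3-treated libraries stays open for the lists: markers under 10 CPM moved apart by more than their errors (Cochran's Q, n = 20, p = 8.8e-08), from Fgfr3 at 1.74 to Olig2 at -0.34, but 0 of them passed as lower when adjusted over these markers, and unequal baselines could dilute an added share unequally. It stays open for the 9 genes too, since the 23 markers, with a median of 0.28 and an upper 95% bootstrap bound of 0.463, went both ways (SD 0.468) and the 9 genes were picked for their change; whether T3 acted on the microglia or on other cells was not tested. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 9 genes, the real one and the split of numbers 1 and 4 from 2 and 3 with 4298. The remaining 33 gave 0 genes. The share of splits cannot decide whether chance gave the count of 9. The split with 4298 genes follows the replicate numbers and is counted beside the real one for any real count up to 4298. A share of 2 in 35 is already too large to exclude chance, so chance stays open for this count. For the 6 lists, 12 of 35 splits gave as many, the highest other calling 10.

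The split with 4298 genes points to a structure among the libraries that follows the replicate numbers and not the treatment. The loadings of the first principal component correlated with gene length across genes (Spearman 0.645), so a length trend, as could come from RNA quality or fragmentation, is a candidate source of the same-number correlations. After the trend was removed from each library, these correlations lay between 0.12 and 0.34. The bootstrap interval of the lowest, 0.053 to 0.2, spans the limit of 0.1. The trend and a shared litter, day or batch therefore cannot be told apart for that pair. T3 replicate 1 with untreated replicate 4 then gave 0.37, 3 with 2 gave 0.30, 4 with 1 gave 0.22 and 2 with 3 gave 0.17. The other pairs of different numbers lay between -0.35 and -0.044. Pairing by number thus still cannot be told from the division of 1 and 4 from 2 and 3. The real split was compared with the splits that part all 4 pairs, 8 in number with the real one: the highest other gave 0 genes unpaired against 9, and 4 genes paired against 55. For lists, unpaired, another of these splits called 6, as many as the real one. It set T3 replicates 1 and 4 and untreated replicates 2 and 3 against the rest. The real labelling was the only 1 of the 8 to reach 55 in the paired fit, and 8 splits are too few for a share under 0.05.

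The 11 genes lower in the paired fit were short, with a median length of 775 bases against 2509 for all tested genes and 4228 for the 44 higher ones. The Spearman correlation of a library's deviations with gene length was 0.439, -0.0998, -0.417 and 0.528 with T3 for numbers 1 to 4. Without T3 it was 0.347, -0.535, -0.56 and 0.488, lower at each number, a difference not tested in pairs. A gene-length trend may be behind their calls: with the block and the length correction, 3 of the 11 still passed, AY036118, Tmsb10 and Ugt1a9. It is argued against as the only source of the folds, since each gene kept between 0.69 and 1.07 of its fold. Their median log2 fold change went from -0.68 (median SE 0.0799) to -0.626 (median SE 0.0892), which are the values of AY036118. The folds of Rps21 (-0.315 to -0.217), mt-Nd4l (-0.448 to -0.336) and Tmsb10 (-0.368 to -0.288) shrank more. A part of such folds may therefore follow the trend. Of the 8 genes that lost their call, 7 had a smaller fold, 6 a larger error and 5 the 2 together. The fold of Lars2 grew. With the block, the length correction also took the number of genes called higher from 44 to 28. A part of the higher calls may follow the trend too. A difference in ribosomal RNA left in the libraries, which AY036118 and Rn18s-rs5 would follow, was not tested and stays open beside a response to T3.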
